A study of Caenorhabditis elegans with 5 samples.

How the data were processed

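Transcript levels of whole nematodes (Caenorhabditis elegans, wild-type hermaphrodites) were measured on 5 Affymetrix GeneChip arrays, 1 array per group. The groups were a culture that was not exposed (the control) and cultures exposed for 24 h to benzene, toluene, formaldehyde or a mix of the 3 compounds (BTF mix). Per the labels' protocols, young adults aged 3 days from an age-synchronised culture were kept at 20 °C in a salt medium without food during exposure, and biotin-labelled cRNA was made from 300 ng of total RNA with a kit that primes at the 3' end of transcripts. Concentrations of the compounds are not given in the sources used here, nor is the incubation of the control.

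The deposited values are probe set intensity values on a linear scale, between 9.15 and 22222, for 22625 probe sets per array. The submitters' processing notes name RMA, Affymetrix Expression Console 1.1 and MAS5 without stating the role of each. Of the probe sets, 10677 (47.2%) carried the same value on at least 1 pair of arrays, and the quartiles of the 5 arrays were nearly equal. Which of the named methods gave the deposited values, and how arrays were normalised to each other, is not given in the sources used here.

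Gene names came from the platform annotation paired with the probe sets, updated through the Entrez identifier in a RefSeq gene table. A single gene was named for 20766 probe sets, of which 20701 matched the gene table, with no changed symbol. Several genes were named for 887 probe sets and none was listed for 895. These 1782 probe sets and 77 control probe sets stayed out of gene counts. A gene with several probe sets (2981 genes) took the probe set with the highest mean over all 5 arrays, which gave 17118 genes. Of the 2187 genes with several probe sets past the level filter, 112 were 2-fold away from control after formaldehyde by some of their probe sets and not by others, and 1 had probe sets 2-fold away in opposite directions.

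Intensities were taken to log2(value + 16). Every log2 difference and fold is on that scale, which understates differences of dim genes. Genes entered counts if their mean log2 level over the 5 arrays reached the 40th percentile (6.05), which left 10271. With 1 array per group there are no replicates: no test, p-value or error can be had, no difference has a replicate check, and a difference of 2-fold is a fixed rule of size. The words higher and lower describe these arrays, not the exposures in general. The number of arrays limits the precision.

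The rule for named genes, the level filter, the other settings and 30 gene lists were fixed before the data were examined. Named were the 12 genes with the largest positive and the 12 with the largest negative difference from control for each exposure, the 8 each way for benzene against toluene, and up to 8 each way for genes 2-fold away in all 4 exposures and for the mix against the range of the single compounds. For each list, up to 4 members with the largest difference in any exposure were named. Other genes that the text names were chosen after their values were seen, as said beside them. The lists covered foreign compound metabolism, stress responses, defence, reproduction, cuticle, lipid and energy metabolism, housekeeping genes and tissue markers. For each list and exposure, the median difference of the measured members was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a percentile below 1 or above 99 was counted as standing apart. Genes of a list can move together, which random lists leave out. Bootstrap intervals (95%, 1000 draws) resampled the genes of a set within the same arrays. They also leave out that genes move together, and they are not errors of an array or a culture.

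Because all exposures share 1 control array, the correlation, covariance and overlap of 100 simulated sets of unchanged arrays against a shared control were computed. Noise for them and for the simulated data below was drawn from the difference between the formaldehyde and BTF mix arrays, separately for each gene among genes of similar level. These were the nearest of the 10 pairs of arrays under the deposited scaling, so noise between cultures may be larger. The steps were tested on simulated data for formaldehyde against control over 10271 genes with 200 genes planted. Of 50 genes planted at a log2 difference of 0.5, 0 reached 2-fold. At 1.25 it was 48 of 50, at 1.5 it was 50 of 50 and at 2.0 it was 50 of 50, and 7 of 10071 unchanged genes reached 2-fold. Among simulated lists, 1 of 50 with no shift and 50 of 50 with a shift of 0.5 lay outside percentiles 1 to 99.

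The same results were computed again with no level filter, a filter at the 60th percentile, centring on the median, quantile normalization, the mean of a gene's probe sets, leaving out probe sets whose names mark possible binding to several transcripts (s or x), a 1.5-fold threshold, pseudocounts of 1 and 64, list members past the filter only, and correlations between differences that share no array. Another 2, no pseudocount and scaling on the poly-A spike probe sets, were chosen after seeing the data. The poly-A spikes are bacterial transcripts added to the RNA before labelling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.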

Results

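Whole-animal RNA of young adult C. elegans was profiled on 5 arrays: 1 control, 1 benzene, 1 toluene, 1 formaldehyde and 1 BTF mix array. The series screened for changes in transcript profile after exposure to each volatile compound and to their combination. The median intensity was 84.8 in the control, 84.3 after benzene, 83.7 after toluene, 82.9 after formaldehyde and 82.3 after the mix. All differences below are log2 differences from the control array unless another baseline is named, and they are relative to the overall level of each array. When arrays were scaled on the poly-A spikes, an alternative chosen after seeing the data, the median of all genes moved to 0.42 after benzene, 0.10 after toluene, 0.08 after formaldehyde and -0.58 after the mix. A list median smaller than the shift of its array and opposite in sign has no settled direction on an absolute scale.

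Formaldehyde gave the most genes 2-fold away from control among the single compounds, at concentrations that are not known. Its median absolute log2 difference from control over genes was also the largest of the 3 (0.17). With poly-A scaling benzene was further from control by that measure (0.42 against 0.16). Of the 12 genes with the largest positive differences, 4 encode enzymes of foreign compound metabolism: cyp-35A4, a cytochrome P450, had an intensity of 66.2 in control and 663.0 after formaldehyde (3.05), cyp-35A3 365 and 2811 (2.89), cyp-35C1 891 and 5477 (2.598), and the UDP-glucuronosyltransferase gene ugt-22 186 and 1525 (2.93). Among the 12 lowest genes, the cuticle collagen dpy-14 had 1635 in control and 148 after formaldehyde (-3.33), dpy-17 had 2310 and 297 (-2.90), and hbl-1, a transcription factor of developmental timing, had 2184 and 195.0 (-3.38). At 2-fold, 467 of 10271 genes were higher and 233 lower, and 96 were at least 4-fold higher and 34 at least 4-fold lower.

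The highest gene after formaldehyde was spig-20 (3.17), and other genes with large positive differences were Y39B6A.1 (3.03), the infection response gene irg-8 (3.02), the folate transporter gene folt-2 (2.74), the hedgehog-related grd-3 (2.74), F55G11.2 (2.68), the methionine sulfoxide reductase gene msra-1 (2.602) and hphd-1 (2.59). The lowest gene was Y110A2AL.4 (-3.71), and other low genes were mtre-1 (-3.49), chtb-1 (-3.46), tts-2 (-3.102), K10D3.4 (-3.05), F13E9.11 (-3.05), the linker histone-like hil-7 (-2.96), W04A8.4 (-2.92) and pqn-13 (-2.84). Of 73 cytochrome P450 genes, 5 were 2-fold higher and 5 lower, and the list median was -0.01. Within the cyp-35A subfamily, which was not a fixed list and was singled out after its members were named, 4 of 5 measured genes were 2-fold higher. UDP-glucuronosyltransferases had 9 of 64 higher and 4 lower, with ugt-41 at 2.19, and glutathione S-transferases 8 of 45 higher and 1 lower, with gst-26 at 2.39 and gst-36 at 2.296. Among 30 short-chain dehydrogenases 2 were higher, dhs-25 (2.39) and dhs-23 (2.17).

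All 23 measured major sperm protein genes were 2-fold higher after formaldehyde, with a list median of 2.22. msp-64 went from 454 to 2518 and msp-152 from 884 to 4811. Only 1 of the 23 genes has a probe set that is not marked as able to bind several near-identical transcripts, so its members are not separate measurements. On that probe set the gene stood at 0.85 after formaldehyde, below 2-fold. Collagens moved both ways: 39 of 145 were higher, among them col-101 (2.37), and 4 were lower, with a median of 0.58. Of 29 moulting genes 6 were lower, including the protease inhibitor gene mlt-11 (-2.59), noah-1 (-2.197), lpr-3 (-1.95) and the fibrillin-like fbn-1 (-1.94), 1 was higher, and the median was -0.30. Intestine markers had 6 of 21 higher, among them the microvillar actin gene act-5 (2.38) and the acid phosphatase gene pho-1 (2.15), with a median of 0.56. Of the 19 cytosolic heat shock genes 5 were higher and 1 lower, with a median of 0.13: hsp-70 stood at 1.99, hsp-17 at 1.93, hsp-16.2 at 1.61 and hsp-16.41 at 1.57. With poly-A scaling 573 genes were higher and 177 lower, and without s and x probe sets 276 were higher and 175 lower.

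The BTF mix array was close to the formaldehyde array. At 2-fold, 446 genes were higher and 237 lower than control, and 411 of the higher (92.2%) and 208 of the lower (87.8%) were also so after formaldehyde. The 12 highest genes after the mix were cyp-35A4 (3.21, intensity 745), ugt-22 (3.07, 1680.0), spig-20 (3.05), Y39B6A.1 (3.02), irg-8 (2.98), cyp-35A3 (2.93), cyp-14A3 (2.75), cyp-35C1 (2.73), F55G11.2 (2.73), grd-3 (2.72), gst-26 (2.62) and folt-2 (2.57), of which cyp-14A3 was below control after formaldehyde (-0.45). On the negative side were Y110A2AL.4 (-3.88), K10D3.4 (-3.38), dpy-14 (-3.34), tts-2 (-3.31), chtb-1 (-3.29), mtre-1 (-3.20), dpy-17 (-3.12), hbl-1 (-3.09), the hatching protease gene hch-1 (-3.01), F13E9.11 (-2.96), W04A8.4 (-2.91) and hil-7 (-2.81). Major sperm proteins had a median of 2.06, with 23 of 23 genes higher and the 1 gene with an unmarked probe set at 1.11 on it, and intestine markers a median of 0.56, with 6 of 21 higher. Collagens had a median of 0.44, with 32 of 145 higher and 4 lower. Moulting genes had a median of -0.32, with 6 of 29 lower and 1 higher, and heat shock genes 0.13, with 5 of 19 higher and 1 lower.

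The mix lay at least 2-fold above all 3 single compounds for 4 genes, which encode cytochrome P450s or UDP-glucuronosyltransferases: cyp-14A3 by 4.92-fold, cyp-14A2 by 2.78-fold, ugt-63 by 2.72-fold and cyp-34A10 by 2.07-fold. cyp-14A3 had 39.8 in control, 53.9 after benzene, 60.2 after toluene, 24.7 after formaldehyde and 359 after the mix. Next came ugt-66 (1.94-fold), ugt-25 (1.82-fold), ugt-8 (1.70-fold) and the ABC transporter gene pgp-14 (1.68-fold). No gene lay 2-fold below all single compounds, and the largest gaps were scl-2 (1.59-fold), W04B5.2 and lpr-3 (both 1.39-fold), clec-7 (1.35-fold), F56D2.3 (1.35-fold), F40E3.5 (1.34-fold), Y65B4BL.7 (1.34-fold) and unc-53 (1.32-fold). With poly-A scaling, which lowered the mix, 185 genes were higher and 1031 lower than control, 1 gene lay 2-fold above all single compounds and 26 lay below. At the 60th percentile filter 0 genes lay above, since the 4 genes were dim.

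Benzene gave fewer differences, and nearly all of those on the positive side were shared with formaldehyde and the mix. At 2-fold, 123 genes were higher and 18 lower than control. Of the 123, 122 were also higher after formaldehyde and 122 after the mix. ugt-22 (1.85, intensity 711), spig-20 (1.85), Y39B6A.1 (1.81), cyp-35A3 (1.76, 1273), irg-8 (1.68), grd-3 (1.61), msra-1 (1.60), hphd-1 (1.57), the collagen col-159 (1.57), cyp-35A4 (1.57), the yolk protein family gene vit-1 (1.56) and folt-2 (1.54) were the highest. C30E1.9 (-2.17), mtre-1 (-2.03), tts-2 (-2.02), the ribosomal RNA gene rrn-3.1 (-1.87), col-74 (-1.73), pqn-13 (-1.49), col-165 (-1.44), chtb-1 (-1.32), cut-3 (-1.28), Y97E10AR.1 (-1.22), the desaturase gene fat-5 (-1.202) and R02F11.1 (-1.18) were the lowest.

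Among the lists after benzene, major sperm proteins had a median of 1.39, with 23 of 23 genes 2-fold higher, while the 1 gene with an unmarked probe set stood at 0.33 on it. Hypoxia response genes had 0.39, with 2 of 15 higher: fmo-2, a flavin monooxygenase gene, at 1.42 and the prolyl hydroxylase gene phy-2 at 1.07. Intestine markers had a median of 0.28, with 2 of 21 higher (act-5 at 1.35 and cpr-5 at 1.01), collagens 0.24, with 11 of 145 higher and 2 lower, and heat shock genes 0.20, with 1 of 19 higher (hsp-17, 1.45). Within cyp-35A, singled out as said above, 3 of 5 genes were higher, while 4 of all 73 cytochrome P450 genes were. Moulting genes had a median of -0.14, and those lower after formaldehyde stayed within 2-fold of control: mlt-11 at -0.34, noah-1 at -0.05, lpr-3 at -0.43 and fbn-1 at -0.05. With poly-A scaling 375 genes were higher and 7 lower, and without s and x probe sets 57 were higher and 15 lower.

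Toluene gave the fewest differences: 11 genes were 2-fold higher and 10 lower. fmo-2 was the highest, with 54.6 in control and 178 after toluene (1.46), followed by F41E6.5 (1.31), nspb-10 (1.15), col-38 (1.11), F22B5.4 (1.11), phy-2 (1.102), msd-2 (1.04), Y82E9BR.17 (1.03), B0410.3 (1.03), msp-64 (1.03), msp-50 (1.03) and spig-20 (0.98). fat-5 was the lowest, with 406 in control and 99.2 after toluene (-1.87), followed by col-74 (-1.43), tts-2 (-1.33), mtre-1 (-1.30), R02F11.1 (-1.18), abu-14 (-1.14), cut-3 (-1.13), chtb-1 (-1.098), pqn-13 (-1.09), ugt-44 (-1.03), col-165 (-0.99) and Y97E10AR.1 (-0.98). Major sperm proteins had a median of 0.90, with 2 of 23 genes 2-fold higher and the 1 gene with an unmarked probe set at 0.15 on it, and hypoxia response genes 0.37, with 3 of 15 higher. Collagens had a median of 0.20, with 1 of 145 higher and 1 lower, and heat shock genes 0.16, with 0 of 19 higher. In cyp-35A, which was not a fixed list, no gene was 2-fold higher. The medians were 0.04 for intestine markers and -0.02 for moulting genes. With poly-A scaling 41 genes were higher and 7 lower, and with a pseudocount of 1 it was 17 and 17. Without s and x probe sets it was 7 and 7, and with a pseudocount of 64 it was 4 and 7.

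Benzene and toluene (methylbenzene) were set against each other directly, which needs no control array. Concentrations were not known, so the pair may not be matched in dose. The highest genes after benzene relative to toluene were ugt-22 (benzene minus toluene 1.46), cyp-35C1 (1.45), vit-1 (1.42), cyp-35A3 (1.37), ugt-21 (1.30), irg-8 (1.24), folt-2 (1.23) and F55G11.2 (1.14). C30E1.9 (-2.26) and rrn-3.1 (-1.31) were the 2 genes 2-fold lower after benzene, and Y102A11A.5 (-0.80), T09E11.11 (-0.77), mtre-1 (-0.74), ule-3 (-0.70), tts-2 (-0.69) and Y82E9BR.17 (-0.66) followed. In all, 19 genes were 2-fold higher after benzene and 2 lower, and 95% of the 10271 genes lay between -0.26 and 0.42. Major sperm proteins stood 0.50 higher after benzene in the median (0.18 for the 1 gene with an unmarked probe set, on it), intestine markers 0.25, vitellogenins 0.16 and genes of fasting and fatty acid oxidation 0.14. Going the other way, moulting genes had a median of -0.10 and ribosomal proteins of -0.04, both at percentile 0.0 of random lists. With poly-A scaling 73 genes were higher after benzene and 1 lower.

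**Figure D1:**
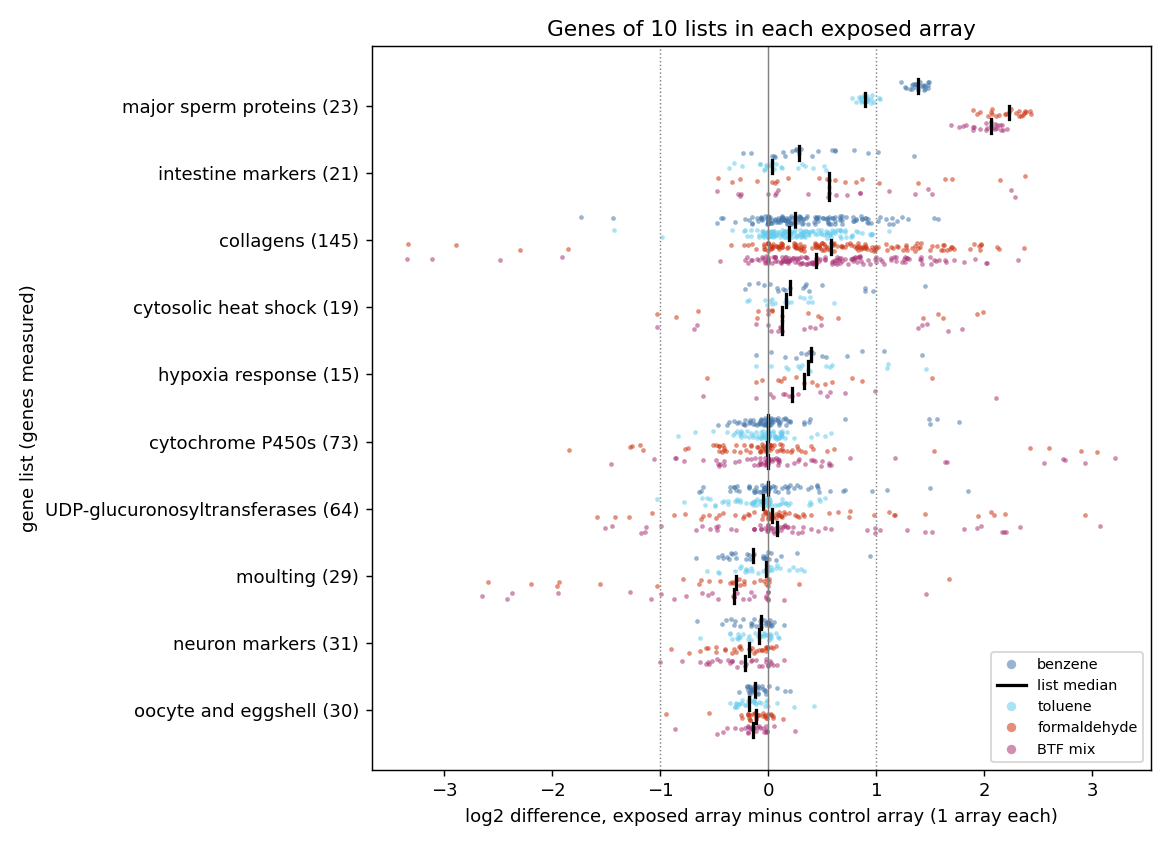
Log2 difference from the control array (horizontal axis) of each measured gene in 10 gene lists, with 1 row of points per exposed array and the list median as a black bar. Major sperm protein genes sit above 0 in all 4 exposed arrays (medians 1.39, 0.90, 2.22 and 2.06 after benzene, toluene, formaldehyde and the mix), while the lowest moulting and collagen genes are those of the formaldehyde and mix arrays.

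Few genes were 2-fold away from control in the same direction in all 4 exposures: 6 were higher (fmo-2, col-38, nspb-10, msd-2, msp-64 and msp-50) and 8 lower (col-74, tts-2, mtre-1, R02F11.1, cut-3, fat-5, chtb-1 and pqn-13). All of the higher genes except fmo-2 rest on probe sets marked s or x, as do mtre-1, R02F11.1 and cut-3 among the lower. Without such probe sets, genes higher in both benzene and toluene fell from 7 to 2. fmo-2 had intensities of 54.6 in control and 173, 178, 186 and 288 after benzene, toluene, formaldehyde and the mix. tts-2 had 2571 in control and 624, 1014, 285 and 245. Treating the 5 arrays alike, 8 genes were 2-fold above all other arrays in control and 6 below, 4 above and 0 below in the mix, 0 above and 1 below (rrn-3.1) in benzene, and 0 in either direction in toluene and formaldehyde. With poly-A scaling it was 3 above and 29 below in control.

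The formaldehyde and mix arrays were the nearest pair, with a median absolute log2 difference of 0.06, and benzene and toluene came next at 0.07. The order of these pairs was kept with median centring and quantile normalization, but with poly-A scaling formaldehyde and mix were 0.68 apart and toluene was nearest to control and to formaldehyde, both at 0.13. Benzene and formaldehyde were 0.11 apart, benzene and mix 0.12, toluene and formaldehyde 0.13, toluene and mix 0.14, control and toluene 0.11, control and benzene 0.12, and control stood 0.17 from both formaldehyde and the mix. Across genes, which are not independent replicates, differences from control correlated with r = 0.97 (rho 0.93) for formaldehyde and mix, 0.83 (0.73) for benzene and formaldehyde, 0.81 (0.71) for benzene and mix, 0.79 (0.76) for benzene and toluene, 0.58 (0.51) for toluene and formaldehyde and 0.56 (0.49) for toluene and mix. Unchanged arrays against a shared control gave 0.50 in simulation (0.44 to 0.57 over 100 draws). Covariances were 0.26, 0.12, 0.11, 0.05, 0.07 and 0.06 in the same order, against a simulated 0.01. Part of each excess may come from the shared control, and the simulated covariance may be low because its noise came from the nearest pair of arrays. Over differences that share no array, formaldehyde and mix correlated with 0.82 to 0.88, and the other pairs between -0.88 and 0.60 depending on the arrays chosen.

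At 2-fold, benzene and formaldehyde shared 122 higher genes against 5.59 for independent lists of those sizes, and 15 lower against 0.41. For benzene and the mix it was 122 against 5.34 and 16 against 0.41. Formaldehyde and the mix shared 411 against 20.3 and 208 against 5.38. Toluene shared 7 higher genes with each of benzene (0.13 for independent lists), formaldehyde (0.50) and the mix (0.48), and 9 lower with benzene (0.02), 8 with formaldehyde (0.23) and 9 with the mix (0.23). Simulated unchanged arrays shared 1.83 higher and 1.57 lower genes on average. The simulated value leaves out real effects and took its noise from the nearest pair of arrays, so it may be low. The independent value leaves out the shared control. No gene was 2-fold higher in one exposure and 2-fold lower in another.

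**Figure D2:**
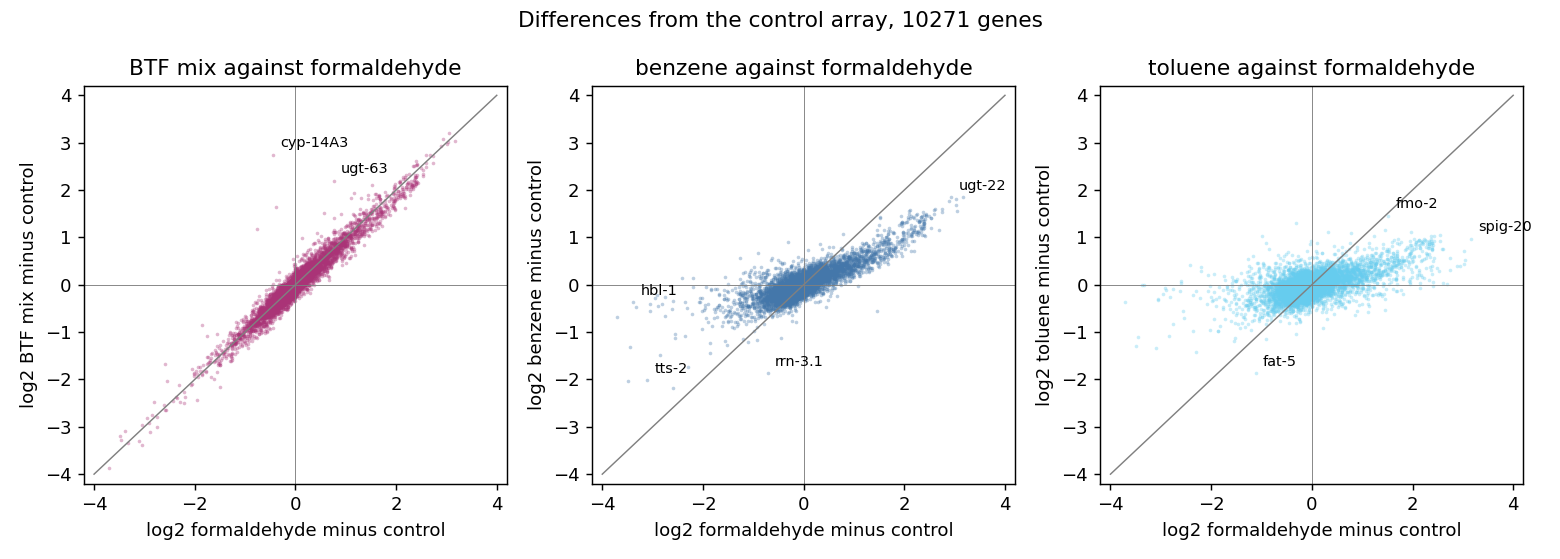
Log2 difference from control after the BTF mix, benzene and toluene (vertical axes) against that after formaldehyde (horizontal axes), 1 point per gene over 10271 genes, with the line of equal differences. The mix follows the line (r = 0.97) with cyp-14A3 and ugt-63 above it, while benzene (r = 0.83) and toluene (r = 0.58) show smaller differences than formaldehyde, and hbl-1 is low after formaldehyde alone among the single compounds.

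Of 120 combinations of list and exposure, 60 stood outside percentiles 1 to 99 of matched random lists, 46 above and 14 below, against 2.4 by chance for independent genes. Many of these had medians near 0. Oxidative defence genes had medians of 0.10, 0.08, 0.08 and 0.10 after benzene, toluene, formaldehyde and the mix, with msra-1 the 1 member of 28 that was 2-fold higher after benzene, formaldehyde and the mix. In that order of exposures, the medians were 0.39, 0.37, 0.33 and 0.22 for hypoxia response genes, 0.02, 0.04, 0.07 and 0.10 for glutathione S-transferases, -0.01, -0.05, 0.04 and 0.08 for UDP-glucuronosyltransferases and -0.01, 0.00, -0.01 and 0.00 for cytochrome P450s. Short-chain dehydrogenases gave 0.03, 0.01, 0.00 and 0.00, ABC transporters 0.02, -0.05, 0.02 and 0.04, and alcohol and aldehyde dehydrogenases 0.07, 0.04, 0.09 and 0.02. adh-1, an alcohol dehydrogenase gene, had 7003 in control, 3994 after formaldehyde (-0.81) and 3549 after the mix (-0.98).

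The unfolded protein response of the ER had medians of 0.04, 0.00, -0.02 and 0.00 and that of mitochondria 0.02, 0.00, 0.00 and -0.03, with 0 members 2-fold away in any exposure. hsp-4 stood between 0.05 and 0.50. DNA damage and repair genes had -0.09, -0.09, -0.10 and -0.10, with 0 of 44 members 2-fold away. Metal response genes had 0.10, 0.02, 0.05 and 0.04. Within that list cdr-4 was 2-fold higher after formaldehyde (2.18), while the metallothionein gene mtl-1 (-1.57) and the ferritin gene ftn-1 (-1.26) were lower. Lysozymes and antimicrobial peptides had medians of 0.00, -0.01, -0.01 and 0.00, with 7 of 55 higher and 5 lower after formaldehyde, among them ilys-5 (2.00), spp-23 (1.95) and lys-4 (1.69). C-type lectins had medians of 0.00 in each exposure, with 7 of 220 higher and 5 lower after formaldehyde, such as clec-265 (1.81) and clec-61 (-1.38).

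Oocyte and eggshell genes had medians of -0.12, -0.17, -0.12 and -0.15, with 0 of 30 members 2-fold away, and early zygotic genes 0.04, 0.03, 0.02 and 0.01. Vitellogenins had 0.15, -0.05, 0.16 and 0.15, and vit-1 was the 1 of 5 that was 2-fold higher after benzene, formaldehyde and the mix. Fatty acid synthesis and desaturation had 0.05, 0.00, 0.00 and -0.04, with 4 of 24 higher after formaldehyde, including the elongase genes elo-5 (1.68) and elo-2 (1.61) and the desaturase gene fat-7 (1.28). Fasting and fatty acid oxidation had 0.06, -0.07, -0.17 and -0.20, with acdh-8 at 1.69 and lipl-2 at -1.26 after formaldehyde. Oxidative phosphorylation had 0.10, 0.12, 0.04 and 0.04, and its cytochrome c member cyc-2.2 stood at 2.38 after formaldehyde. Ribosomal proteins had -0.04, 0.01, -0.13 and -0.10, the proteasome 0.11, 0.09, 0.04 and 0.08, body wall muscle markers 0.07, 0.10, 0.08 and 0.10, neuron markers -0.07, -0.09, -0.18 and -0.21, and reference genes 0.07, 0.05, 0.02 and 0.00. unc-52, a muscle marker, stood at 1.06 after formaldehyde on its brightest probe set, while its other probe sets gave -0.90 and -0.37.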

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

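The tests below were chosen after seeing the data, with the lists of larval moult, mid-embryo and other spermatogenesis genes, except that the oocyte and eggshell list and the correlation between differences that share no array were planned, and that the bounds for the larval moult and mid-embryo lists were set before those lists were computed. All hypotheses here were found and tested on the same 5 arrays.

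The poly-A spike probe sets, which are outside the gene measurement, were above control in the BTF mix array, by a median of 0.55 over 12 probe sets (log2), 12 of them above 0, and below control after benzene by a median of -0.43, 0 of 12 above 0, while the hybridisation spikes stood at 0.14 and -0.13. The 5' over 3' ratio of the actin, GAPDH and ubiquitin probe sets was above control for all 3 transcripts after benzene (mean log2 0.31) and toluene (0.24). Ubiquitin was only slightly so (0.046 and 0.06). On every array the 5' signal was below the 3' signal, at ratios from 0.028 (ubiquitin, mix) to 0.414 (GAPDH, benzene). Among 753 bright probe sets that name several genes or none, 30 were 2-fold higher after benzene, 2 after toluene, 84 after formaldehyde and 73 after the mix, and 1, 1, 9 and 8 were lower.

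Sperm genes were higher in all 4 exposed arrays, with list medians of 1.39, 0.90, 2.22 and 2.06 after benzene, toluene, formaldehyde and the mix, but 21 of 23 genes were within 2-fold after toluene and the 1 gene with an unmarked probe set stood at 0.33, 0.15, 0.85 and 1.11 on it. An error of the single control array as the whole cause is argued against by the exposed arrays themselves: over the 23 major sperm protein genes formaldehyde stood 1.30 above toluene (SD of members 0.14). The members are not separate measurements, so that SD is not an error of either array. On its unmarked probe set the 1 gene stood closer, at 0.85 after formaldehyde and 0.15 after toluene. RNA integrity stays open: the 5' over 3' ratio of the mix was 0.007 from control in the mean and that of formaldehyde 0.19, against 0.31 for benzene and 0.24 for toluene, but in the mix actin stood at 0.35, GAPDH at -0.17 and ubiquitin at -0.17. Probe sets that bind several near-identical genes stay open, since 22 other spermatogenesis genes on probe sets not marked s or x had medians of 0.06 after benzene, 0.08 after toluene and 0.43 after formaldehyde with a bootstrap interval of 0.00 to 1.02, although after formaldehyde 7 of the 22 were 2-fold higher, 0 were lower and the list stood above percentile 99. A difference in stage or age between the cultures also stays open, with oocyte and eggshell genes at percentile 6.85 after formaldehyde, 0.02 after benzene, 0.0 after toluene and 0.58 after the mix, and so does an effect of exposure, which the design cannot part from it. The incubation of the control is not given. Differences shared by all 4 exposed arrays therefore cannot be parted from 24 h in salt medium without food.

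After both formaldehyde and the mix 208 genes were 2-fold lower, among them the collagens dpy-14 and dpy-17, while collagens as a list were higher (median 0.58 after formaldehyde). The 208 genes had a median of -0.43 after benzene and -0.29 after toluene, against -1.34 after formaldehyde. The bootstrap interval over genes after benzene was -0.47 to -0.39, which is not an error of either array. The 208 were chosen for being low after formaldehyde and the mix, so part of this gap is built in. It cannot decide by itself on an error of the single control array. The moulting list, fixed before the data were examined, argues against such an error as the whole cause for its own members. Its medians were -0.30 and -0.32 after formaldehyde and the mix, against -0.14 and -0.02 after benzene and toluene. Part of the difference stays open to an error of the control array. Fewer moulting larvae stay open: 24 larval moult genes had a median of -0.27 after formaldehyde, between the bounds set in advance. On probe sets not marked s or x, 15 of them had -0.13 (percentile 3.37) after formaldehyde and -0.16 (1.555) after the mix. After benzene these 15 were about as low, at -0.14 (0.225), and after toluene they had -0.02 (27.4). A candidate explanation is fewer embryos in mid development. The 40 mid-embryo lineage regulators stood at percentile 0.0 after both formaldehyde and the mix and at 63.5 after benzene. Their median after formaldehyde was small (-0.25). Among the 208 genes were 3 of the 40, against 208 of the 10271 genes past the level filter. The 208 genes were chosen for being 2-fold lower, so their larger median cannot be set against this explanation. Early zygotic genes, with medians of 0.02 and 0.01, were not lower. Only 14 of these 46 genes passed the level filter, so most were too dim to show a loss clearly. These values leave the explanation a candidate. Formaldehyde acting on gene activity in the adult was not tested and remains open.

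For the benzene array, which lay between the toluene and formaldehyde arrays under the deposited scaling but not with poly-A scaling, the shared control array as the cause is argued against by a correlation of 0.59 across genes between benzene minus control and formaldehyde minus toluene, which share no array. Such correlations for benzene and formaldehyde ran from -0.82 to 0.60 depending on the arrays chosen, so 0.59 is near the top. The distances that place benzene between these arrays use no control array. The same response at a uniformly smaller log2 size is argued against only under the deposited scaling. There benzene covered 0.38 of the log2 way from toluene to the mix for 331 genes (bootstrap interval over genes 0.36 to 0.39, not an error of the arrays). These genes were 2-fold higher after formaldehyde than after toluene. For 172 genes 2-fold lower it was 0.14 (0.13 to 0.18), a difference of 0.24. With poly-A scaling the proportions were 1.36 and -0.04, a difference of 1.40. Shifting whole arrays moves these proportions apart by construction, so this adds no support. It shows that the difference depends on the level given to each array. A mixture of toluene-like and formaldehyde-like RNA stays open, since on the linear scale the proportions were 0.26 and 0.22, a difference of 0.041, with quartiles of 0.20 to 0.34 and 0.13 to 0.35, but differed by 1.55 with poly-A scaling. Single genes depart from 1 fraction: rrn-3.1 in benzene (2289) lay below toluene (5693) and formaldehyde (5094), and C30E1.9 in benzene (137) lay near formaldehyde (98.1) and far from toluene (717). A graded effect of benzene was not tested and remains open.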

How the results depend on the processing

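Median centring and quantile normalization left each count within 1.5 times its main value, and every list median that stood apart by 0.2 or more within 0.1. No pseudocount and poly-A scaling were chosen after seeing the data, and the other settings before. The correlations from the shared control moved by less than 0.1 under every alternative that kept the control as baseline. Unless said otherwise the cause of a move was not tested. No paired analysis was possible because each group had 1 array.

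Scaling on the poly-A spikes moved all genes of an array alike, by the shifts given in the report, and its effects follow from those shifts. Genes higher than control came to 375 after benzene, 41 after toluene and 185 after the mix, and lower ones to 7 after benzene and 1031 after the mix. Benzene against toluene gave 73 higher and 1 lower. Shared higher genes were 340 for benzene and formaldehyde, 38 for benzene and toluene, 182 for formaldehyde and mix, 29 for toluene and mix and 34 for toluene and formaldehyde. Shared lower genes were 6 for benzene with the mix and 6 with formaldehyde, 3 for benzene and toluene and 5 for toluene and formaldehyde. Genes beyond all other arrays were 1 above and 25 below in the mix, 3 above and 29 below in control and 0 below in benzene, and the mix lay above all single compounds for 1 gene and below for 26. Median absolute differences became 0.98 for benzene and mix, 0.33 for benzene and formaldehyde, 0.32 for benzene and toluene, 0.60 for control and mix, 0.42 for control and benzene, 0.68 for formaldehyde and mix and 0.66 for toluene and mix.

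Poly-A scaling turned the median of collagens after the mix to -0.11 and of hypoxia response genes after the mix to -0.33, both still above the shift of all genes there (-0.58). Collagens came to 0.67 after benzene and 0.71 after formaldehyde, heat shock genes to 0.63 after benzene, and hypoxia response genes to 0.83, 0.49 and 0.45 after benzene, toluene and formaldehyde. Intestine markers came to 0.72, 0.69 and 0.0124 after benzene, formaldehyde and the mix, and major sperm proteins to 1.82, 1.01, 2.35 and 1.51 in the order benzene, toluene, formaldehyde, mix. Moulting genes came to -0.17 after formaldehyde and -0.87 after the mix, and neuron markers to -0.76 after the mix.

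A 1.5-fold threshold lets in more genes by construction. Higher and lower genes were 357 and 94 after benzene, 161 and 81 after toluene, 891 and 660 after formaldehyde, 869 and 681 after the mix, and 105 and 16 for benzene against toluene. Shared higher and lower genes were 348 and 83 for benzene and mix, 343 and 85 for benzene and formaldehyde, 136 and 51 for benzene and toluene, 784 and 560 for formaldehyde and mix, 138 and 59 for toluene and mix and 135 and 58 for toluene and formaldehyde. Genes beyond all other arrays were 46 above and 128 below in control, 12 above and 1 below in the mix, 5 above and 4 below in toluene, 2 below in benzene and 3 below in formaldehyde. The mix lay above all single compounds for 12 genes and below for 1.

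Without s and x probe sets fewer genes were measured. Genes higher than control were 57 after benzene, 7 after toluene, 276 after formaldehyde and 271 after the mix. Shared higher genes were 56 for benzene with the mix and 56 with formaldehyde, 2 for benzene and toluene, 239 for formaldehyde and mix, 3 for toluene with the mix and 3 with formaldehyde, and shared lower ones 5 for toluene and formaldehyde. Control lay above all other arrays for 5 genes and below for 2. Major sperm proteins were left with 1 gene, at 0.33, 0.15, 0.85 and 1.11 after benzene, toluene, formaldehyde and the mix. Collagens had medians of 0.45 after formaldehyde and 0.34 after the mix, and intestine markers 0.73 after the mix. unc-52 turned to -0.90 after formaldehyde, and to -0.0685 with the mean of its probe sets, since its probe sets moved in opposite directions.

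With a pseudocount of 64, genes higher than control were 76 after benzene and 4 after toluene, and lower ones 144 after formaldehyde and 153 after the mix, with 9 higher in benzene than in toluene. Shared higher genes were 75 for benzene with the mix and 75 with formaldehyde, 1 for benzene and toluene, 1 for toluene and mix and 1 for toluene and formaldehyde. Shared lower genes were 131 for formaldehyde and mix and 5 for toluene and formaldehyde. Control lay above all other arrays for 5 genes and below for 0, and after formaldehyde collagens had a median of 0.45 and intestine markers 0.46. With a pseudocount of 1, toluene gave 17 higher and 17 lower genes, shared higher genes were 11, 12 and 11 for toluene with benzene, the mix and formaldehyde, and shared lower ones 15, 16 and 15. Control then lay above all other arrays for 14 genes and below for 10, and formaldehyde below for 1. With no pseudocount the same counts were 18 and 17, then 12, 13 and 12, then 15, 16 and 15, then 14 and 11, and 1.

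A filter at the 60th percentile, which tests fewer genes, gave 147 lower genes after formaldehyde and 149 after the mix, 136 lower in both, and 5 lower in both toluene and formaldehyde. It left 0 genes with the mix above all other arrays, 0 above all single compounds, and 5 with control above all others. Without a filter the dim genes lowered the median absolute differences to 0.0703 for benzene and mix, 0.0672 for benzene and formaldehyde, 0.0789 for toluene and mix, 0.0772 for toluene and formaldehyde, and to 0.0983, 0.0775, 0.0993 and 0.0736 for control with the mix, benzene, formaldehyde and toluene. The mean of a gene's probe sets left 0 genes with benzene below all other arrays and 1 lower in benzene than in toluene, and gave heat shock genes 0.32 after benzene. Members past the filter had medians after the mix of 0.55 for collagens, -0.52 for moulting genes and -0.34 for neuron markers.

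Correlations between differences that share no array depend by construction on which exposed array replaces the control. They ran from -0.59 to -0.21 for benzene and toluene, -0.82 to 0.60 for benzene and formaldehyde, -0.85 to 0.60 for benzene and mix, -0.86 to 0.25 for toluene and formaldehyde and -0.88 to 0.21 for toluene and mix. The lowest for formaldehyde and mix was 0.82.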

Other observations

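The 3 gene lists used here were chosen after seeing the data. Of 40 mid-embryo lineage regulators 3 were 2-fold lower after formaldehyde, with a list median of -0.25, against 0 of 40 after benzene and toluene. ceh-22, a homeobox gene of the pharynx, had intensities of 182 in control, 118.6 after benzene, 149 after toluene and 37.8 after the mix, and stood at -2.01 after formaldehyde. ceh-32 stood at -1.26 and ceh-34 at -1.005 after formaldehyde, and at -1.13 and -1.09 after the mix. Genes named here are those with the largest differences in their list, chosen after their values were seen.

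Spermatogenesis genes outside the fixed list of major sperm proteins were higher as well: 15 of 33 were 2-fold higher after formaldehyde, 14 after the mix, 6 after benzene and 1 after toluene. The list medians were 0.61, 0.50, 0.12 and 0.17 in that order. Without s and x probe sets 7 of 22 were 2-fold higher after formaldehyde, 6 after the mix, 3 after benzene and 0 after toluene, with medians of 0.43, 0.36, 0.06 and 0.08. The largest differences after formaldehyde were those of msd-4 (2.54) and msd-2 (2.54), and msd-2 rests on a probe set marked x. Next, sss-1 had 37.3 in control and 226 after formaldehyde and ssp-34 had 145 and 686. The sperm histone gene htas-1 had 60.6 and 319, and ssp-16 had 95.6 and 454. Larval moult genes had medians of -0.18, -0.13, -0.27 and -0.30 after benzene, toluene, formaldehyde and the mix. Within them ptr-4 stood at -1.56 after formaldehyde while col-49 (1.86) and phat-4 (1.67) were higher.

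The mix array differed from the formaldehyde array in a few lists. Mix minus formaldehyde had a median of -0.11 over collagens (percentile 0.0) and of -0.20 over major sperm proteins, against 0.25 for the 1 of these genes with an unmarked probe set, on it, while 3 of 73 cytochrome P450 genes and 1 of 64 UDP-glucuronosyltransferase genes were 2-fold higher in the mix. The ribosomal RNA gene rrn-3.1 had 8378 in control, 2289 after benzene, 5693 after toluene, 5094 after formaldehyde and 7078 after the mix, and C30E1.9 had 674, 137, 717, 98.1 and 200.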
